A study of Homo sapiens with 9 samples.

How the data were processed

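Total RNA of 9 Colo320DM xenograft tumours, with an RNA integrity number above 7 per the labels, was hybridised to the nCounter Human Tumor Signaling 360 Panel, which counts barcoded probes without amplification. Per the labels the RNA came from a MasterPure kit, and mice were assigned at random when tumours had reached about 90 mm3. The labels give Colo320DM as the source of all 9, while their description field counts up from Colo320DM to Colo328DM, which was read as a filling error. The deposited table holds 780 gene rows and 14 control rows, 6 positive and 8 negative, as linear signal values, meaning probe counts that the authors multiplied by a factor per sample. The software and the background step are not stated. The values themselves show the factor: the 20 housekeeping genes had a geometric mean of 579.8 in every sample, with a range of 0.0035 between samples. Gene values were whole multiples of a step per sample, within 0.0051 normalized counts, for at least 98.3% of genes, and 17 values were listed at exactly 1. The control rows hold whole numbers that were not scaled. Dividing by the steps, which lay between 0.727 and 1.69, gave estimated totals of 258870 to 698035 counts per sample. These estimated counts served for the calls above background and for voom weights. Raw counts as measured were not used here, so the precision at low levels is itself an estimate. The sums of the normalized counts lay between 413947 and 551402.

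Samples were grouped by the treatment in the labels, with 3 in vehicle, 3 at 5 mg/kg and 3 at 10 mg/kg. Gene symbols were compared with a RefSeq gene table, where 773 matched, 2 were older symbols and 5 joint names of gene pairs had no match. Values were taken as log2 of the normalized count plus 1. Genes with a mean of at least 20 normalized counts over the 9 samples were tested, 669 genes, and 111 were left out. Each comparison was a contrast in a single model of the 3 groups in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The comparisons were 5 mg/kg against vehicle, 10 mg/kg against vehicle, 10 against 5 mg/kg, and a slope on dose. SE is the moderated standard error of the log2 fold change. Adjusted p values in the text come from limma. A tool for raw counts, planned in case the table held them, was not run, because the table holds scaled values.

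Before the data were examined, 42 gene lists were fixed. The 30 with at least 5 tested members were tested in limma camera with a preset correlation of 0.01, adjusted over the lists. Lists with too few members were tankyrases and their partners, cyclin-dependent kinase inhibitors, pro-apoptotic genes, ERK output, Notch, Hedgehog, intestinal lineage, intestinal stem cell, neuroendocrine, lipid metabolism, endothelial and fibroblast genes. The rule for named genes, fixed at the same time, takes the 12 largest increases and the 12 largest decreases among genes past the threshold, up to 4 members per list, and 17 genes of interest, of which 7 were on the panel. The text gives fewer of them. LAMB3, NANOG, NCF1, TPSAB1/B2 and CD8B in the closing section were named after their values were seen. So were KLK2, KLK3, KIR3DL1 and IFNA1, examples of the 18 genes of other tissues, and JUN, a member of the Wnt score. Background per sample was the mean of the negative controls plus 2 SD. Differences of single values between groups were tested with exact permutation tests.

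Alternatives fixed before the data were examined were no filter, a minimum mean of 50, a pseudocount of 10, median centring, centring on candidate housekeeping genes, quantile normalization, no intensity trend, array weights, only the groups compared, the mouse number as a block, leaving out each replicate, and, for lists, an estimated correlation and fry. Leaving out a replicate leaves 2 tumours in a group, and the spread is pooled over the groups. Chosen after seeing the data were minimum means of 200 and 500, subtraction of the median of the 18 genes of other tissues followed by a new housekeeping scaling, voom weights on the estimated counts, and the mouse number as a block in a fit of the dosed groups alone. The labels give no animal, batch or day shared by mice with the same number. After group means were removed, same-number tumours of vehicle and a dosed group had correlations from -0.50 to -0.011, which gives no sign that these numbers pair them. With 3 tumours per group these few values cannot exclude a pairing. The 3 same-number pairs of 5 and 10 mg/kg had 0.19 to 0.31, all above 0.1 (other pairs -0.21 to 0.041). Pairs of vehicle and 10 mg/kg tumours with different numbers reached 0.33. Whether the numbers pair the dosed groups is therefore not settled by these values. No 2 samples were copies of each other. The model was tested on simulated data with the fitted means and spreads of the 669 genes, 10 mg/kg against vehicle: of 100 genes changed 2-fold 81 were recovered, of 100 changed 4-fold 99 were recovered, and 8 unchanged genes were called. Without any change 0 genes were called, and with 21 DNA repair genes shifted by 1 on the log2 scale that list alone was called. Noise was drawn separately for each gene and many genes changed at once, so recovery may be lower where few genes change. Figures were drawn with matplotlib 3.10.9.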

Results

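Tumours of Colo320DM, a human colorectal cancer cell line with MYC amplified on extrachromosomal DNA, were grown as xenografts in mice and measured with a panel of 760 tumour-related genes and 20 housekeeping genes. The mice received vehicle or STP1002, an inhibitor of the tankyrases, which are enzymes that mark AXIN proteins for degradation and thereby favour beta-catenin signalling. The doses were 5 and 10 mg/kg, by mouth each day for 28 days. Each group held 3 tumours, taken from 3 mice drawn at random out of 8, so n = 3 for each group value below. The sum of the normalized counts of all genes lay between 413947 and 551402 per tumour. MYC alone held 25.7% ± 0.75 of these counts in vehicle, 28.0% ± 3.5 at 5 mg/kg and 28.1% ± 2.2 at 10 mg/kg (SD). The table names genes by symbol without genome positions, and probe numbers limit the precision of low signals. TNKS, TNKS2, AXIN1, AXIN2, LGR5, NKD1, NOTUM, RNF43, ZNRF3 and LEF1 were not on the panel.

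The tumours at 5 mg/kg had fewer genes with a signal above background than the other 6 tumours. Above the level of the negative control probes, 708 ± 7 of 780 genes were detected in vehicle, 518.7 ± 14.5 at 5 mg/kg and 715 ± 2.6 at 10 mg/kg (SD). A set of 18 genes of other tissues, such as the prostate genes KLK2 and KLK3 and the killer cell receptor gene KIR3DL1, was written down after part of the values had been seen. Their median normalized count per tumour was 45.8 ± 9.3 in vehicle, 4.71 ± 0.57 at 5 mg/kg and 40.0 ± 15.3 at 10 mg/kg, where replicate 2 had the lowest value, 23.9. The negative controls, scaled like the genes, averaged 6.13 ± 1.29, 5.32 ± 1.57 and 5.24 ± 2.40 in the same order.

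**Figure D1:**
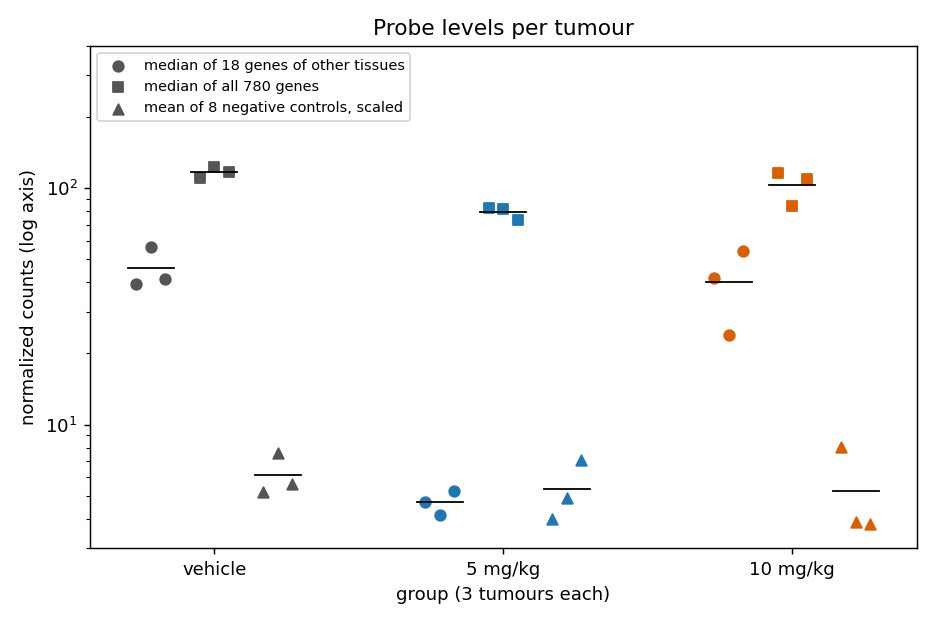
Normalized counts per tumour on a log axis for the 18 genes of other tissues (circles, median), all 780 genes (squares, median) and the 8 negative controls (triangles, mean), with a line at the mean of each group of 3. The 18 genes lay between 4.13 and 5.26 at 5 mg/kg and between 23.9 and 56.6 in the other 6 tumours.

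The first comparison asks what 28 days of the lower dose changed in the tumours. At 5 mg/kg, HRAS, a RAS family GTPase, and MCM2, a subunit of the replicative helicase, were higher than in vehicle, with log2 fold changes of 1.11 (SE 0.25, adjusted p = 0.0016) and 0.96 (SE 0.20, adjusted p = 8.0e-04). XBP1, a transcription factor of the unfolded protein response, rose by 0.91 (SE 0.26), and P4HB, an oxidoreductase of the endoplasmic reticulum, by 0.74 (SE 0.22). LCN2, a secreted iron-carrier protein, rose by 1.12 (SE 0.33) from a low level of 19.3 ± 3.2 to 43.2 ± 6.8 normalized counts (SD). POU5F1, a pluripotency transcription factor, was lower by far, at 132.3 ± 34.8 against 3444 ± 415 normalized counts in vehicle (log2 fold change -4.72, SE 0.28, adjusted p = 2.2e-08). Among 669 genes tested, 37 were higher and 290 lower, and in 325 of these 327 the values of the 2 groups did not overlap. Of all tested genes 67.6% had no overlap, against a chance share of 10%. The median log2 fold change of all tested genes was -0.42, and with each tumour centred on its median gene 131 genes were higher and 214 lower.

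The genes higher at 5 mg/kg were mostly abundant, and the lower genes were mostly weak. Among 80 genes with a vehicle mean of 1000 or more normalized counts, 17 were higher and 5 lower. Among 132 genes with a vehicle mean under 50, 1 was higher and 111 were lower. Of the 290 lower genes, 138 were not above background in any tumour at 5 mg/kg. With a minimum mean of 500 normalized counts, chosen after these values were seen, 5 genes passed, 2 higher and 3 lower. With the level of the 18 genes of other tissues subtracted, 39 genes passed, 5 higher and 34 lower, and 37 of the 39 were among the 327.

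**Figure D2:**
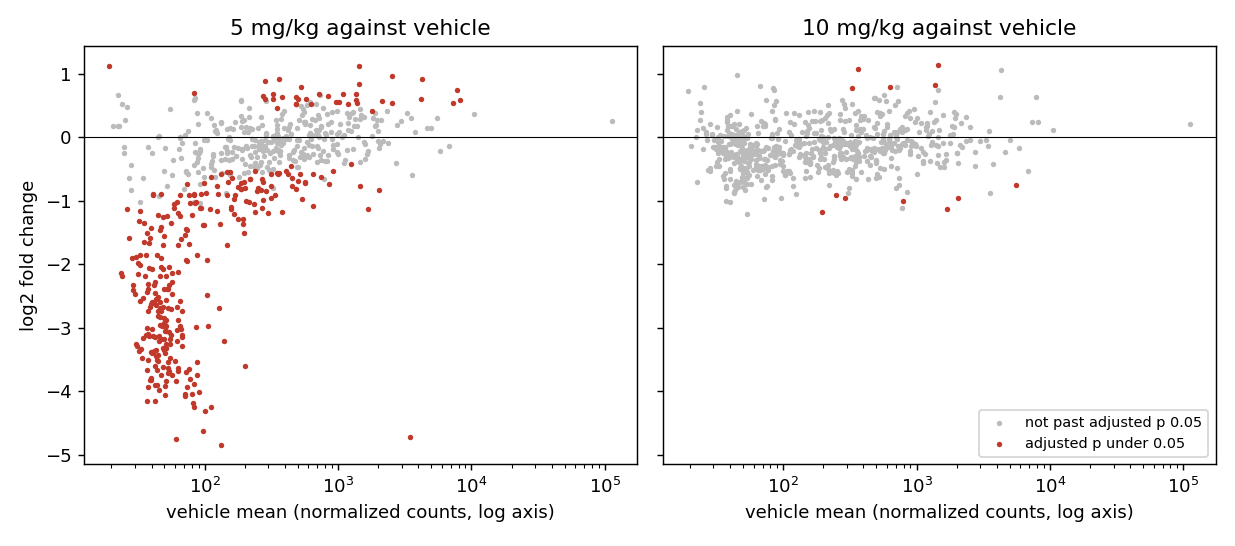
Log2 fold change of each tested gene against its mean in vehicle (normalized counts, log axis) at 5 mg/kg (left) and 10 mg/kg (right), with genes past an adjusted p of 0.05 in red. At 5 mg/kg the lower genes gather at low levels, with a median of -2.47 under 50 normalized counts, while the right panel holds 12 red points.

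Cell cycle genes went both ways at 5 mg/kg. Among 16 tested genes of G1/S and DNA replication, MCM2 rose and 15 did not pass. Among 23 genes of G2/M and mitosis, 2 rose and 5 fell, among the latter CCNB2 (-1.20, SE 0.22), a B-type cyclin, CHEK1 (-0.99, SE 0.22), a checkpoint kinase, and KIF2C (-0.72, SE 0.21), a mitotic kinesin. Adjusted over the list alone, 1 rose and 5 fell. MKI67, a marker of cycling cells, did not pass (0.31, SE 0.18, adjusted p = 0.161). Of 21 DNA repair genes, 1 rose and 4 fell, and of 14 MYC target genes PHB (0.61, SE 0.24) and NME1 (0.53, SE 0.18) rose and none fell. Adjusted over each list alone, 1 rose and 3 fell for DNA repair, and none passed for MYC targets. MYC itself stood at 0.26 (SE 0.26, adjusted p = 0.43). None of these 4 groups passed the list test, where G1/S genes had the lowest adjusted p, 0.051.

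The Wnt target genes that fell at 5 mg/kg were weak signals. On the panel were 5 of 30 listed Wnt/beta-catenin target genes. CD44, a hyaluronan receptor, fell by 2.67 on the log2 scale (SE 0.42) and CCND1, the gene of cyclin D1, had a log2 fold change of -1.86 (SE 0.46), with vehicle means of 62.5 ± 14.8 and 33.0 ± 5.0 normalized counts. With quantile normalization CCND1 turned to 0.84 and did not pass. TCF7 (-0.25, SE 0.34) did not pass, and its sign turned with median centring, quantile normalization and array weights. Of 8 Wnt ligands, receptors and components, 2 fell and 6 did not pass, among them CTNNB1, the gene of beta-catenin (0.42, SE 0.18, adjusted p = 0.071), and APC (0.17, SE 0.18, adjusted p = 0.46). For both groups the counts adjusted over the list alone were the same. Neither group passed the list test, with adjusted p = 0.81 and 0.20; the test compares a list with the other genes of the panel, and its direction for the targets was up while their median was -0.25. Of 5 YAP/TAZ target genes, 3 fell and 2 did not pass.

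In signalling and stress groups single genes changed, and none of the following groups passed the list test. The cell cycle inhibitor gene CDKN1A fell (-2.14, SE 0.40), as did PMAIP1 (-3.05, SE 0.36) and THBS1 (-2.98, SE 0.31). They were weak signals at 5 mg/kg, at 12.4, 5.36 and 10.1 normalized counts, where the 18 genes of other tissues stood at 4.71. With the level of those 18 genes subtracted THBS1 still passed as lower, while CDKN1A and PMAIP1 were not among the genes that passed. The subtraction takes 1 value per tumour off every gene, so a gene that lost more than that can still come out lower. IFNA1, itself 1 of the 18 genes, also passed as lower (-4.29, SE 0.82). Passing here and below therefore does not separate a change of the gene itself from the loss of weak signals. Of 17 receptor tyrosine kinases 12 fell, among them FLT1 (-4.31, SE 0.37), a VEGF receptor. This is a weak group, with a median level of 44.1 normalized counts, and FLT1 fell to 4.10. With the level of the 18 genes subtracted FLT1 still passed as lower. Of 18 PI3K/AKT/mTOR genes 1 rose and 6 fell, among them PIK3CA (-1.50, SE 0.26), and 4 fell adjusted over the list alone. Of 14 RAS/MAPK genes 2 rose, HRAS and MAPK3 (0.55, SE 0.16), and 1 fell. Of 9 NRF2 genes 2 rose and 4 fell, among them GPX1 (-3.21, SE 0.38) and HMOX1 (-3.20, SE 0.46). These 2 fell to 15.2 and 6.54 normalized counts. With the level of the 18 genes subtracted GPX1 still passed as lower, and HMOX1 was not among the genes that passed. Of 15 hypoxia and glycolysis genes PGK1 rose (0.59, SE 0.21) and 2 fell, among them HIF1A (-0.96, SE 0.29), and none passed adjusted over the list alone. Quantile normalization turned PGK1 to -0.033. Of 18 chromatin regulators 6 fell, among them the acetyltransferase genes CREBBP (-1.11, SE 0.23) and EP300 (-1.14, SE 0.31). In each of 3 groups, mitochondrial respiration, amino acid metabolism and the unfolded protein response, 1 gene rose and 1 fell, with IDH1 (-0.90, SE 0.21), SLC7A5 (-1.17, SE 0.25) and XBP1 among them. The same counts held for 5 autophagy genes and 6 anti-apoptotic genes, where MCL1 rose (0.60, SE 0.23). Adjusted over the list alone these counts were the same except as given and for RAS/MAPK genes, where none fell, and anti-apoptotic genes, where none rose.

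Lists of immune and stromal genes fell to unlike extents at 5 mg/kg, while the 18 genes of other tissues had a median log2 fold change of -2.97. Because the tumours are xenografts of a human cell line in mice, these lists are not a measure of immune or stromal cells here. Lymphocyte, myeloid and checkpoint genes carried low signals (median levels 31.5, 26.5 and 31.2) and had medians of -2.82, -2.55 and -2.32. Angiogenesis, JAK/STAT and NF-kB genes (median levels 43.0, 34.5 and 40.5) had -1.91, -1.44 and -1.41. Mesenchymal, TGF-beta, epithelial and interferon genes (median levels 73.7, 83.0, 151.2 and 126.9) had -1.03, -0.65, -0.23 and -0.11. Among these groups those with the highest median levels had the smallest falls. Where a gene is near background at 5 mg/kg, the size of its change depends on the value added before the log, here 1; with 10 added, OSMR stood at -2.07, IL6 at -2.05, TLR4 at -2.55 and NKG7 at -2.40, against -4.62 for POU5F1. Of 12 lymphocyte markers 9 fell and none rose, among them NKG7 (-3.83, SE 0.38) and MS4A1 (-3.33, SE 0.45), with 10 lower adjusted over the list alone. The list passed with adjusted p = 0.040 at the preset correlation, had adjusted p = 0.53 with an estimated correlation, and did not pass without the filter on low values, where all 20 members on the panel were tested. All 5 macrophage and myeloid markers fell, among them CD163 (-3.04, SE 0.42). Of 18 JAK/STAT genes 14 fell, among them OSMR (-4.15, SE 0.42), and of 18 NF-kB genes 13 fell, among them IL6 (-3.31, SE 0.45) and TLR4 (-3.80, SE 0.43). Of 13 immune checkpoint genes 9 fell, among them CTLA4 (-3.61, SE 0.48), and 7 of 10 angiogenesis factors fell. Of 24 interferon and antigen presentation genes IRF1 (0.70, SE 0.27) and 1 other rose and 9 fell, among them HLA-DRB1 (-3.94, SE 0.48). Among TGF-beta and BMP genes 5 of 9 fell, among mesenchymal genes 3 of 6, and among epithelial genes 2 of 5, with CDH1, the gene of E-cadherin, at -3.70 (SE 0.42). Adjusted over the list alone the counts were the same except for 15 lower JAK/STAT genes and 2 higher NF-kB genes. None of these groups but the lymphocyte markers passed the list test. Candidate housekeeping genes stood higher than the rest of the panel, with adjusted p = 0.040 and adjusted p = 0.48 with an estimated correlation. Of these 18 genes 5 rose, with GUSB at 0.91 (SE 0.25), and 3 fell, with NRDE2 at -1.01 (SE 0.25) and ERCC3 at -0.77 (SE 0.17). GUSB, NRDE2 and ERCC3 are among the 20 housekeeping genes that the scaling holds level as a group. With a median of -0.42 for all tested genes, the list can stand higher by the scaling alone.

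The second comparison asks the same of the higher dose. At 10 mg/kg, HRAS was again higher than in vehicle, at 3204 ± 685 against 1439 ± 138 normalized counts (SD; log2 fold change 1.14, SE 0.25). GUSB, a lysosomal glucuronidase, rose by 1.08 (SE 0.25), SKIL, a repressor of SMAD proteins, by 0.82 (SE 0.19), MAFG, a small MAF transcription factor, by 0.79 (SE 0.17), and CRK, an adaptor protein, by 0.77 (SE 0.17). PDK1, a kinase that restrains pyruvate oxidation, was lower at 402.4 ± 112 against 794.5 ± 111 normalized counts (log2 fold change -1.01, SE 0.21), and the glycolytic enzyme gene ALDOA had -0.75 (SE 0.18). ZAP70 (-1.18, SE 0.27), a T cell kinase, the chemokine receptor CXCR4 (-1.12, SE 0.25), the histidine decarboxylase HDC (-0.95, SE 0.21) and the histone demethylase KDM6A (-0.90, SE 0.22) were also lower. In all, 5 genes were higher and 7 lower among 669, with adjusted p between 0.0439 and 0.0447, and in all 12 the 3 tumours of each group did not overlap. Of all tested genes 18.8% had no overlap, against a chance share of 10%.

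**Figure D3:**
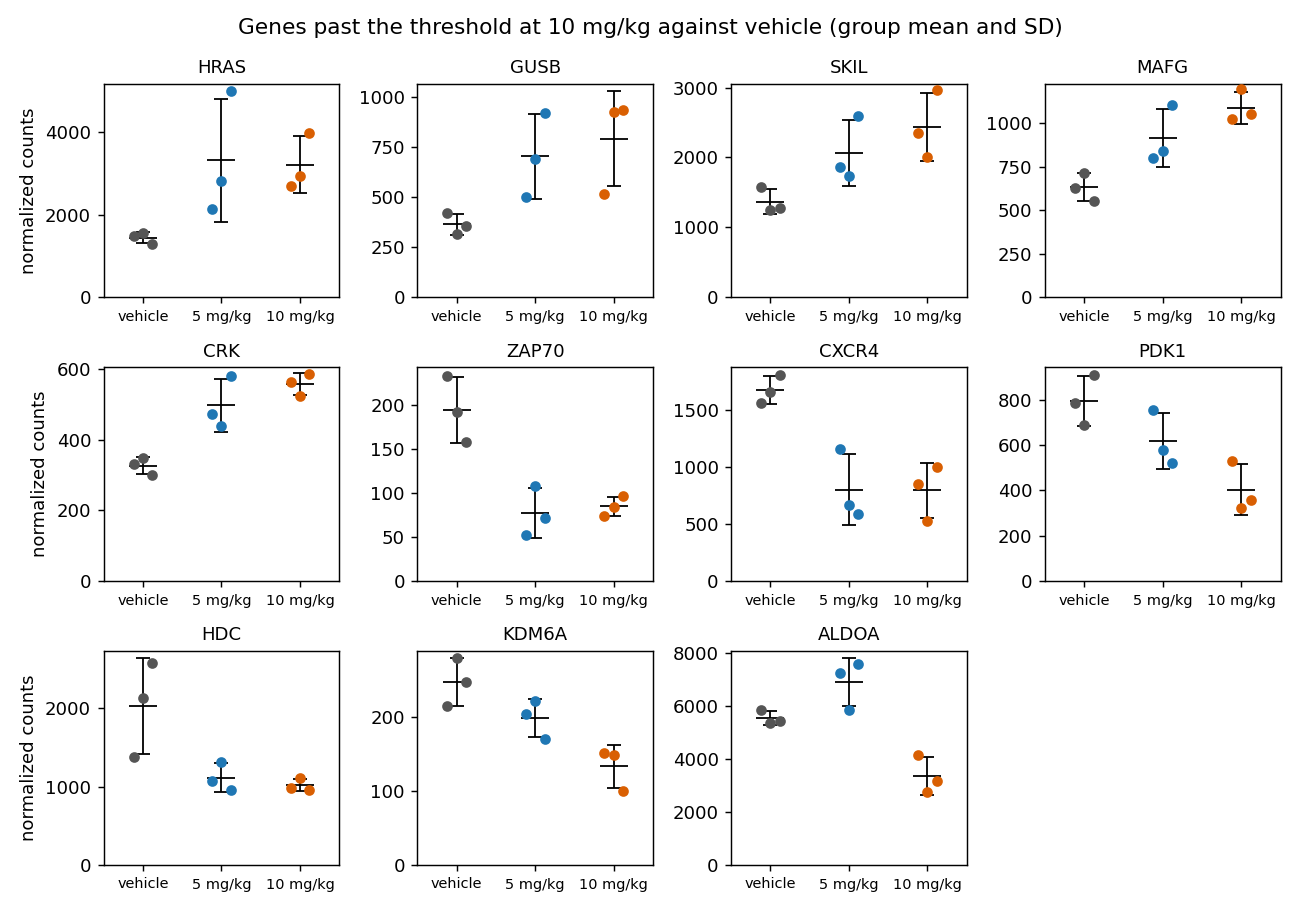
Normalized counts per tumour (points), group mean (bar) and SD (whiskers) of 11 of the 12 genes past the threshold at 10 mg/kg against vehicle, in vehicle, 5 mg/kg and 10 mg/kg tumours. HRAS stood at 1439 in vehicle, 3312 at 5 mg/kg and 3204 at 10 mg/kg, and ALDOA at 5551, 6890 and 3353.

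All 5 genes higher at 10 mg/kg were also among the 37 higher at 5 mg/kg, where 0.277 would be shared by independent lists. Of the 7 lower genes 4 were lower at both doses, among them CXCR4, HDC and ZAP70, against 3.03 for independent lists. In 100 simulations of unchanged groups a mean of 0 higher and 0.01 lower genes were shared. Such groups give almost no calls that could be shared, so this count is no chance level for the overlap. Both comparisons use the same vehicle tumours, which independent lists leave out, so part of the overlap may come from these tumours. Of the 12 genes, 11 had the same sign at 5 mg/kg; ALDOA had the other. The call was narrow, since without vehicle replicate 2 or 3, 5 mg/kg replicate 2 or 10 mg/kg replicate 2 no gene passed, without vehicle replicate 1 or 10 mg/kg replicate 3 a single gene did, and without 10 mg/kg replicate 1 the count was 30. No gene passed without the intensity trend or with voom weights. With median centring 4 genes passed, all higher, and the median log2 fold change of all tested genes was -0.15.

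At 10 mg/kg none of the 30 lists held more than 2 genes past the threshold. Of 15 hypoxia and glycolysis genes PDK1 and ALDOA fell and 13 did not pass, among them LDHA (-0.87, SE 0.28, adjusted p = 0.175) and ERO1A (-0.87, SE 0.24, adjusted p = 0.094). Adjusted over the list alone, 5 fell. None of 14 MYC target genes passed, and adjusted over the list alone 1 was higher and 4 lower. KDM6A was the 1 of 18 chromatin regulators to fall, HRAS the 1 of 14 RAS/MAPK genes to rise and GUSB the 1 of 18 candidate housekeeping genes to rise, with 3 higher and 3 lower adjusted over that list alone. XBP1 (1.06, SE 0.26, adjusted p = 0.052) and the glutamine transporter gene SLC1A5 (-1.11, SE 0.28, adjusted p = 0.053) did not pass. No Wnt gene passed, with CTNNB1 at 0.32 (SE 0.18), TCF7 at 0.18 (SE 0.34), CCND1 at -0.45 (SE 0.46), MYC at 0.20 (SE 0.26) and APC at -0.07 (SE 0.18). CDKN1A (-0.24, SE 0.40) and MKI67 (0.18, SE 0.18) did not pass. No list of the 30 passed in limma camera, with a lowest adjusted p of 0.47, 1 list with an unadjusted p under 0.05 and a lowest adjusted p of 0.230 in fry.

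**Figure D4:**
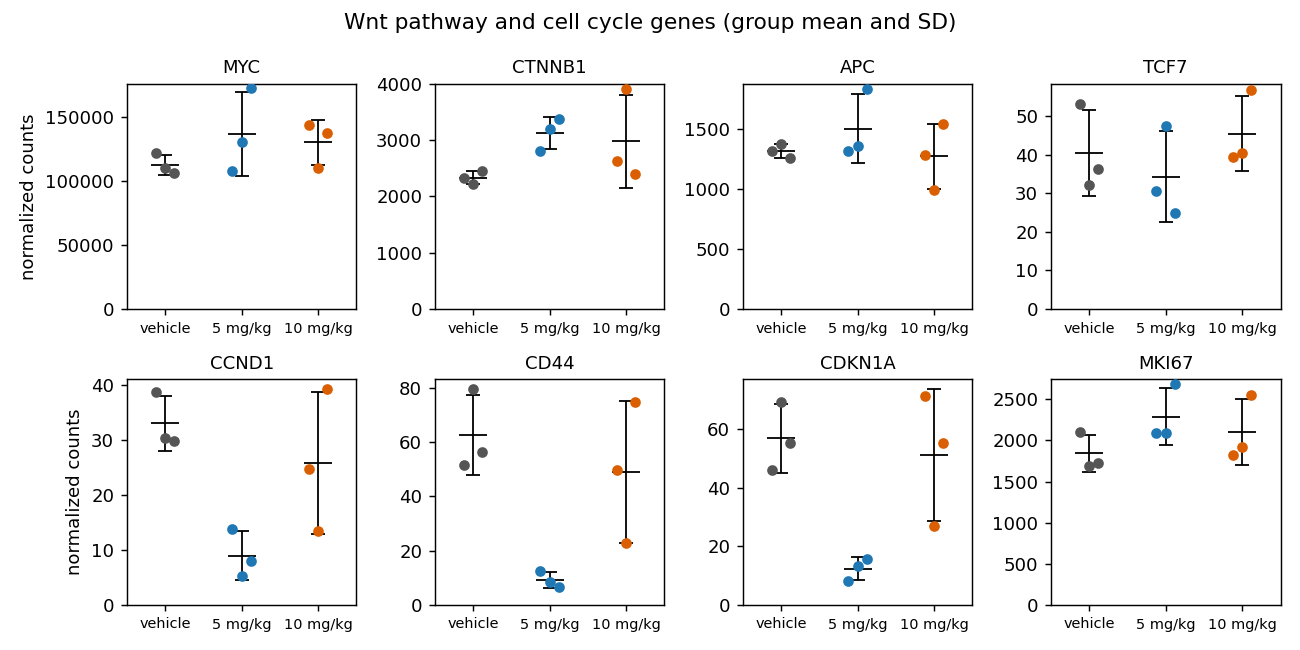
Normalized counts per tumour (points), group mean (bar) and SD (whiskers) of Wnt and cell cycle genes in the 3 groups. CD44, CCND1 and CDKN1A stood at 9.06, 8.95 and 12.4 at 5 mg/kg, against 62.5, 33.0 and 56.8 in vehicle and 49.0, 25.8 and 51.2 at 10 mg/kg.

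The third comparison tests whether the doses differed. Between 10 and 5 mg/kg, ALDOA was lower at the higher dose by the widest margin among the lower genes (-1.05, SE 0.18, adjusted p = 1.9e-04), followed by GABARAP, an autophagy gene (-0.83, SE 0.17), UBE2T (-0.80, SE 0.26) and MCM2 (-0.80, SE 0.20). PDK1 (-0.63, SE 0.21) and KDM6A (-0.59, SE 0.22) were lower too, as were IDH2 (-0.65, SE 0.25), CCNK (-0.65, SE 0.24), PSMB7 (-0.59, SE 0.16), PRDX2 (-0.51, SE 0.19), SDHA (-0.51, SE 0.14) and DLL3 (-0.51, SE 0.18), the last not with the mouse number as a block in the dosed groups alone (adjusted p = 0.055). POU5F1 was higher at 10 mg/kg (4.59, SE 0.28), with 3394 ± 1602 normalized counts, as were FCGR3A/B (4.59, SE 0.46), TNFSF8 (4.49, SE 0.43), TNFSF13B (4.36, SE 0.45), HLA-DRB1 (4.21, SE 0.48), CDH5 (4.10, SE 0.47) and ESR1 (4.06, SE 0.48). With 10 added before the log, FCGR3A/B stood at 3.08 and HLA-DRB1 at 2.26. In all, 234 genes were higher and 14 lower, and 228 of the 234 were among the 290 that were lower at 5 mg/kg than in vehicle, against 101.4 for independent lists. Both counts rest on the same 5 mg/kg tumours, so this overlap is no separate evidence. The 2 groups did not overlap in 235 of the 248, and in 43.0% of all tested genes. The median log2 fold change was 0.24, and with median centring 201 genes were higher and 56 lower.

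Between the doses 6 lists passed at the preset correlation, 5 as lower and 1 as higher at 10 mg/kg, and none with an estimated correlation. MYC targets, G1/S genes and DNA repair genes each had adjusted p = 0.012 as lower at the preset correlation, against 0.50, 0.50 and 0.42 with an estimated correlation. Among them 0 of 14 MYC targets passed singly, MCM2 was the 1 of 16 G1/S genes to fall, and 3 of 21 DNA repair genes rose. The mean log2 fold changes of these lists were -0.16, -0.12 and -0.059, against a median of 0.24 for all tested genes. Lower thus means lower relative to the other genes of the panel. Hypoxia and glycolysis genes had adjusted p = 0.023 as lower, against 0.57 with an estimated correlation, with 3 rising and ALDOA and PDK1 falling among 15 and a mean log2 fold change of -0.028. Candidate housekeeping genes also had 0.023 as lower, against 0.42 with an estimated correlation, with 2 rising and SDHA falling among 18. The list holds genes used for the scaling, so its place relative to the panel can come from the scaling alone. Lymphocyte markers had 0.023 as higher, against 0.57 with an estimated correlation, with 9 of 12 rising, among them NKG7 (3.57, SE 0.38), while the 18 genes of other tissues had a median of 2.69. In fry, which tests a list without comparing it with the other genes, 14 lists passed as higher and 1 as lower, the last the housekeeping genes; lymphocyte markers passed, and the other 4 of the 6 did not. Adjusted over the list alone, 9 lymphocyte markers rose, 2 DNA repair genes rose and MCM2 fell, and the other 3 counts were the same. Without the filter on low values, lymphocyte markers and hypoxia and glycolysis genes did not pass and JAK/STAT genes passed as higher. Single genes that rose were CCNB2 (1.08, SE 0.22), CREBBP (1.48, SE 0.23), PIK3CA (1.34, SE 0.26), CDH1 (3.35, SE 0.42), CD163 (2.90, SE 0.42), THBS1 (2.54, SE 0.31), PMAIP1 (2.35, SE 0.36), CD44 (2.20, SE 0.42), CDKN1A (1.90, SE 0.40) and CCND1 (1.40, SE 0.46). With the level of the 18 genes of other tissues subtracted, CCNB2, CREBBP, PIK3CA and THBS1 still passed, and the others of these were not among the genes that passed. IFNA1, itself 1 of the 18 genes, also passed (3.53, SE 0.82), so for weak signals passing does not separate the genes. Quantile normalization turned CCND1 to -1.06 and PMAIP1 to -0.14. MYC (-0.05, SE 0.26), CTNNB1 (-0.10, SE 0.18), APC (-0.25, SE 0.18), TCF7 (0.43, SE 0.34) and MKI67 (-0.13, SE 0.18) did not pass. With a minimum mean of 500 normalized counts 3 genes passed, 1 higher and 2 lower.

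A slope on dose over all 9 tumours asks whether any gene followed the dose. No gene passed in limma, with 67 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.146, and none with voom weights. With array weights 96 genes passed, 27 higher and 69 lower.

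The effects of the doses were compared across genes, which are not independent replicates. Pearson's r was 0.40 and Spearman's rho 0.51 over 669 genes. The shared vehicle tumours alone gave a mean r of 0.50 (upper limit 0.57) in 1000 simulations of unchanged groups, so r did not exceed what these tumours give. The share of genes with the same sign was 78.5% against a simulated mean of 66.6%, and the covariance was 0.199 against a simulated mean of 0.049 (upper limit 0.061). Over 302 genes with a mean of at least 200 normalized counts r was 0.58, within the simulated upper limit of 0.59 (mean 0.50), and the covariance was 0.106 against a simulated mean of 0.0212 (upper limit 0.0275). Without 10 mg/kg replicate 2, r over all tested genes was 0.049.

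A Wnt target score, the mean log2 level of TCF7, MYC, CCND1, CD44 and JUN relative to each gene's mean, was computed per tumour. It was 0.29 ± 0.14 in vehicle, -0.56 ± 0.12 at 5 mg/kg and 0.27 ± 0.55 at 10 mg/kg (SD). The weak signals CD44 and CCND1, which moved with the 18 genes of other tissues, carry most of the drop at 5 mg/kg, while MYC and TCF7 did not pass there. Exact two-sided permutation tests gave p = 0.1 for 5 mg/kg against vehicle, 1 for 10 mg/kg against vehicle and 0.1 for 10 against 5 mg/kg, where 0.1 is the smallest p that 3 against 3 allows. Over the 9 tumours the score had r = -0.02 with dose (exact permutation p = 0.957 over 1680 arrangements) and rho = 0.16 (p = 0.729). Both had a Benjamini-Hochberg adjusted p of 0.957 over these 2 correlations. The 6 tumours of vehicle and 10 mg/kg are equally far from the median dose, and leaving out each of their 15 pairs gave r from -0.77 to 0.34. No relation of the score with dose was found.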

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

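The tests on host cells, on the scaling of a fixed background, on the splits for 5 mg/kg and for the gene lists, on separate vehicle tumours and on the size of a shift of abundant genes were chosen after the results had been seen, as were the 18 genes of other tissues.

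The doses differed in 248 genes between 10 and 5 mg/kg, led by POU5F1 with a log2 fold change of 4.59, and the 18 genes of other tissues differed by a median of 2.69; each was noted because the 2 dose groups differ in a direct test. LAMB3, a laminin gene under the level minimum, had 11.1 ± 1.7 normalized counts at 10 mg/kg, 5.58 ± 1.25 in vehicle and 3.86 at 5 mg/kg (SD, n = 3; exact permutation p = 0.1 against vehicle, the smallest possible); it was noted as lying outside the tested genes, is 1 of 111 such genes and lies near background, since the scaled negative controls averaged 6.13 in vehicle and 5.24 at 10 mg/kg, with 8.01 in 1 tumour.

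The loss of weak signals at 5 mg/kg was the widest pattern. Mouse cells in the tumour would leave genes of prostate, testis and killer cells level, but these 18 genes had a median log2 fold change of -2.97 with an upper quartile of -2.23 (17 of 18 lower; median -2.46 in the 9 whose values had not been seen), and a fixed probe background would scale alike, yet the negative controls were 1.15 times as high in vehicle as at 5 mg/kg against 9.74 times for the 18 genes. DNA carried over with the RNA in vehicle and 10 mg/kg tumours may add counts to each probe. The excess over 5 mg/kg was predicted to be higher in genes with a named pseudogene. It was not found to be in the genes compared, with a ratio of medians of 0.979 (16 against 272 genes, 95% bootstrap interval 0.123 to 1.80, permutation p = 0.94). The interval is too wide to exclude DNA. The genes compared left out POU5F1, IFNA1, NANOG, which has 10 named pseudogenes, and joint names such as FCGR3A/B and TPSAB1/B2. NCF1 was counted as having no named pseudogene. These genes had large drops at 5 mg/kg, so the test cannot decide for or against DNA. Seen after that test and so no evidence of their own, the positive control probes, which do not come from the tumour, were also lower at 5 mg/kg (749 ± 128 counts against 961 ± 27 in vehicle and 964 ± 125 at 10 mg/kg; SD, n = 3; exact permutation p = 0.1 against vehicle), and POU5F1, whose relative POU5F1B is the neighbour of MYC on the GRCh38.p14 assembly with 0 protein-coding genes between, had 108.5 times the median excess. DNA, a processing batch, for which the labels give no record, and an effect of the 5 mg/kg dose on these genes cannot be told apart here; 10 splits of the 6 tumours are too few for a share under 0.05, and the real split gave 327 genes (1 of 10 as large) against a highest other of 0.

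The 37 genes higher at 5 mg/kg were mostly abundant. A shift of all abundant genes would move the 162 genes with a mean of at least 500 alike. Their median log2 fold change was 0.159 (scaled median absolute deviation 0.398) against 0.60 for the 28 higher genes among them, and 58 of the other 134 were lower. The 28 were picked as higher in these same values, so their median lies above that of all 162 in any case. The comparison therefore cannot decide for or against such a shift. With that minimum and median centring 5 of 28 (0.179) passed; the bound set in advance, a share under 0.5, would go with the shift, but it was wrong, because the minimum without centring already left 2 of 28 and centring moved the folds by 0.045. Background in the housekeeping scaling may contribute: with it subtracted, 3 of 37 (IRF1, MCM2 and RRAGC; a share of 0.081) passed, which goes with it by the bound set in advance, while the median went from 0.61 (SE 0.20) to 0.55 (SE 0.23) and why the calls ended was not tested. This criterion, that folds should shrink, was added after the share was seen. Background scaling, a shift of abundant genes and an effect of the dose therefore cannot be told apart for these genes.

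The genes changed at 10 mg/kg mostly moved the same way at 5 mg/kg, which shared vehicle tumours alone could produce. The covariance of the effects over 302 genes with a mean of at least 200 was 0.106, above the 0.0275 that bounds simulated unchanged groups. With different vehicle tumours for each dose the lowest of 6 covariances was 0.0733 (highest 0.113, lowest 0.041 without 10 mg/kg replicate 2). These values exceed noise drawn separately for each gene, as in the simulation. Real residuals were correlated across genes, from -0.50 to 0.33 between vehicle and 10 mg/kg tumours, so the bound may be too narrow. The 6 covariances also reuse the same tumours. Shared vehicle noise as the whole cause is therefore not settled. A vehicle group that differs from both dosed groups for another reason, a processing batch or the drug also remain open. The 10 splits of the 6 tumours are too few for a share under 0.05; the real split gave 12 genes (1 of 10 as large) and the highest other 0.

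For 10 against 5 mg/kg the real split gave 248 genes (1 of 10 as large) and the highest other 0, and 6 lists (1 of 10) against 2. Of the 10 splits 4 part all 3 same-number pairs, and the 3 of these other than the real split gave at most 0 genes and 1 list. For the lists at 5 mg/kg against vehicle the real split gave 2 and the highest other 9, with 2 of 10 splits as large, also too few splits for a share under 0.05. For the slope on dose the splits say nothing about chance, since the real count was 0 and so all 100 drawn, the real split included, gave at least as many genes; the highest gave 115, which points to a structure of the samples that dose order does not follow.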

How the results depend on the processing

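The minimum means of 200 and 500, background subtraction, voom weights and the block in the dosed groups alone were chosen after the results were seen. For the causes of the changes below, fewer genes tested applies to the minimum means; otherwise the cause was not tested. At 5 mg/kg against vehicle 327 genes became 106 with a minimum mean of 50, 24 with 200, 5 with 500, 95 with quantile normalization (49 higher, 46 lower) and 39 with background subtracted; the other settings gave 289 to 426, and leaving out a replicate 235 to 357. At 10 mg/kg against vehicle 12 became 4 with median centring, 6 with background subtracted, 0 with no intensity trend or voom weights, 23 with the mouse number as a block, and 0 to 30 without a replicate. At 10 against 5 mg/kg 248 became 41, 5 and 3 with minimum means of 50, 200 and 500, 55 with quantile normalization and 23 with background subtracted. The slope gave 96 genes with array weights and 0 to 6 without a replicate (6 without 5 mg/kg replicate 3, 4 and 1 without 10 mg/kg replicate 1 and 3).

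The 2 lists at 5 mg/kg became 0 with an estimated correlation, minimum means of 50, 200 and 500, quantile normalization or background subtracted, 15 with fry (all lower, without the housekeeping genes), 7 with median centring, and 0 to 5 without a replicate (0 without vehicle replicate 2, 5 mg/kg replicate 1 or 10 mg/kg replicate 1 or 2, 1 without vehicle replicate 3, 5 and 4 without 5 mg/kg replicate 2 and 3). The 6 lists at 10 against 5 mg/kg became 0 with an estimated correlation, minimum means of 50 and 500, quantile normalization or background subtracted, 15 with fry (14 higher, 1 lower; 2 of the 6 among them), 1 with a minimum mean of 200 (interferon and antigen presentation genes, lower, not among the 6), and 4 to 10 without a replicate (10 without 5 mg/kg replicate 3, 4 without 10 mg/kg replicate 2). Without the filter 3 lists passed at 5 mg/kg, housekeeping, G1/S and JAK/STAT genes but not lymphocyte markers, and 5 passed between the doses, where JAK/STAT genes came in and lymphocyte markers and hypoxia and glycolysis genes did not pass. No list passed at 10 mg/kg against vehicle in any setting.

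The correlation of the dose effects was 0.049 without 10 mg/kg replicate 2 and 0.238 to 0.582 without another replicate. The Wnt score's r of -0.02 with dose turned to 0.356 with minimum means of 50, 200 and 500, 0.012 with a pseudocount of 10, 0.169 with median centring, 0.158 with quantile normalization, 0.352 with background subtracted, and -0.31 to 0.135 without a replicate (0.103 without 10 mg/kg replicate 2, 0.076 and 0.033 without vehicle replicate 2 and 3). With the mouse number as a block it was -0.024. With the minimum means of 50, 200 and 500 or background subtracted it rests on MYC and JUN alone. Between the doses, where same-number tumours had positive correlations, the block gave 253 genes and 7 lists, or 266 and 6 in the dosed groups alone. Among the genes named it changed the call of DLL3 alone.

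Single genes changed sign as follows. With quantile normalization, CCND1 (0.84), TCF7 (1.44) and PGK1 (-0.033) at 5 mg/kg, CDKN1A (0.027) at 10 mg/kg, and CCND1 (-1.06), CTNNB1 (0.087), PMAIP1 (-0.14) and TCF7 (-0.85) between the doses. With median centring, TCF7 (0.15) at 5 mg/kg and APC (0.10) at 10 mg/kg. With array weights, TCF7 (0.0059) at 5 mg/kg and MYC (0.065) between the doses. With background subtracted, MYC (0.14), CTNNB1 (0.077) and MKI67 (0.041) between the doses. Leaving out a replicate gave APC -0.22 to 0.095 and CDKN1A -0.53 to 0.16 at 10 mg/kg, positive without 10 mg/kg replicate 2. Between the doses it gave MYC -0.21 to 0.13, positive without 5 mg/kg replicate 3 or 10 mg/kg replicate 2, and CTNNB1 -0.31 to 0.042, positive without 10 mg/kg replicate 3. Weak signals limit the 5 mg/kg group most, where 518.7 genes on average stood above the negative controls.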

Other observations

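All tests in this part were chosen after the results were seen. With the level of the 18 genes of other tissues subtracted, the 34 genes still lower at 5 mg/kg than in vehicle included POU5F1 (-4.93, SE 0.35), NANOG (-3.89, SE 0.42), FCGR3A/B (-5.34, SE 0.55), TPSAB1/B2 (-4.92, SE 0.61), NCF1 (-4.62, SE 0.67) and CD8B (-2.63, SE 0.50). For FCGR3A/B, TPSAB1/B2 and NCF1, with means of 1.56, 1.56 and 1.13 at 5 mg/kg after subtraction, the size depends on the value of 1 given to subtracted signals. The 34 also included IFNA1 (-4.29, SE 0.82), itself 1 of the 18 genes. Staying lower therefore does not separate a change of a weak gene from the loss of weak signals. They also included genes at higher levels, CCNB2 (-1.19, SE 0.24), PIK3CA (-1.40, SE 0.31), SLC7A5 (-1.21, SE 0.28), CXCR4 (-1.28, SE 0.30) and CREBBP (-1.07, SE 0.28).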
